A study of Homo sapiens with 2 samples.

How the data were processed

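Gene expression was measured on human Affymetrix oligonucleotide arrays, read in 1 colour, on which most genes are represented by one or more probe sets. The 2 arrays held RNA of human amniotic fluid-derived stem cells, 1 from a culture kept for 48 h without ethanol and 1 from a culture kept for 48 h with 100 mM ethanol. Both cultures were sealed with parafilm, a film that limits evaporation, and per the labels' protocols the medium was renewed daily. The labels name no second culture, so each group has 1 array and no value has a replicate error.

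The deposited table holds log2 expression values, which the authors computed from the scanner files by RMA, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays equal at the level of single probes, takes log2 and summarizes the probes of a set. It leaves no detection call and no measure of background for a probe set, so low values carry no statement on whether a gene is expressed, and it compresses differences near the bottom of the scale. The series' design text names affylmGUI as the program, with limma for the comparison, and a fold threshold of 1.8. The versions of these programs are not given in the sources used here. A linear model has no residual degree of freedom with 1 array per group, so no p-value is given anywhere.

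From the table of 22283 probe sets, 68 Affymetrix control sets were set aside, and some of them are not reported here. Probe sets of XIST or of genes on the Y chromosome, 52 in number, were left out of every result because the cells came from a person. Of the 22163 probe sets analysed, 19034 had exactly 1 gene symbol in the platform annotation, 1022 had several and 2107 had none there. Of the probe sets with 1 symbol, 19022 were found by gene ID in the RefSeq gene table of GRCh38.p14, which altered 0 symbols. No genome build is named for the deposited values, so no coordinates are given. A gene was represented by the probe set with the highest mean log2 value over both arrays, a choice that does not look at the difference, which gave 11939 genes. Levels of different probe sets were used to choose and filter probe sets and to match random lists, and not to compare the abundance of genes.

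The difference was the ethanol value minus the control value on the log2 scale. Probe sets and genes were counted where the arrays differed by more than 1.8-fold. Before the data were examined, the threshold, the alternatives, 40 gene lists and the rule for naming genes were fixed. The rule took genes with a mean level at or above the median of all analysed probe sets, 5.90 on the log2 scale, a difference over 1.8-fold and probe sets above that level that all differed in one direction, up to 15 per direction. It added up to 4 members with the largest absolute difference from each list described, and ADH5, ALDH2, CAT and CYP2E1 whatever their values. For each list with at least 5 genes at or above that level, the median difference was placed among 10000 random lists of the same size drawn from the 7001 genes at or above the level and matched on mean level in 20 bins. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. The percentile describes these 2 arrays and is not a test of ethanol, and genes on one array are not independent.

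The procedures were tested on simulated differences for the 7001 genes, with the spread observed at each level. The differences were drawn independently for each gene from a normal distribution, and list members were picked at random. Lists of related genes and extreme values of real arrays are therefore not covered, and false calls may be more frequent than simulated. Of 50 genes changed 2-fold, 34 were counted beyond 1.8-fold, and of 50 changed 3-fold, 50 were. Of 50 genes changed 1.5-fold, 3 were counted, and of 6801 unchanged genes, 1 was. Of 200 unchanged lists of 20 genes, 12 stood apart, against 76 of 200 lists shifted by 0.1 and 185 of 200 lists shifted by 0.2 on the log2 scale. The number of arrays limits the precision of every value.

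The alternatives were thresholds of 1.5-fold and 2-fold, a further quantile normalization, centring on the median difference, subtraction of a lowess trend on level (span 0.4), the level minimum applied or dropped, 32 added to the linear values before log2, removal of probe sets whose IDs end in _s_at or _x_at, and the median over a gene's probe sets. For the lists they also included random lists without matching and the mean in place of the median. Centring shifts all genes alike, so it is no check of a list's percentile. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.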

Results

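Expression was profiled in human amniotic fluid-derived stem cells, multipotent cells grown from amniotic fluid, after 48 h with or without 100 mM ethanol in sealed dishes. The comparison asks which genes differ in expression after ethanol exposure. Each condition was represented by 1 array, so differences between the arrays hold the effect of ethanol together with any difference between single cultures, RNA preparations and hybridizations. The log2 values ran from 3.25 to 13.8 on the control array and from 3.23 to 13.7 on the ethanol array, with medians of 5.91 and 5.88.

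The 2 arrays were closely alike. Of 22163 probe sets, 58 differed by more than 1.8-fold, 46 higher and 12 lower with ethanol. Counted by gene, 30 of 11939 genes passed this threshold, 24 higher and 6 lower. The share that was higher was 80% (exact 95% binomial interval 61.4 to 92.3%, counting error only). Across probe sets the arrays correlated with Pearson r = 0.992, and 79.6% of probe sets lay within 1.2-fold. The robust SD of the differences was 0.19 on the log2 scale.

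Among genes at or above the level minimum, 20 were more than 1.8-fold higher with ethanol. The largest difference was in SSR3, a subunit of the translocon-associated protein complex of the endoplasmic reticulum, at 6.69 in the control and 8.21 with ethanol, or 2.86-fold higher. SEC24D, a component of the COPII coat that carries proteins out of the endoplasmic reticulum, was 1.85-fold higher. GALNT10, an enzyme that starts O-linked glycosylation, was 1.97-fold higher, but its other probe set, also above the level minimum, was at 0.29 on the log2 scale. BAX, which promotes apoptosis, was 2.14-fold higher. It had 2 probe sets, with differences of 1.10 and 1.42 on the log2 scale, and was the 1 gene with 2 or more probe sets that all passed the threshold. The IDs of both BAX sets end in _s_at. RGS2, a regulator of G protein signalling, was 2.41-fold higher, and GEM, a small GTP-binding protein, was 1.89-fold higher. SSR3, RGS2 and GEM were each measured by 1 probe set.

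SOX4 and SOX11, related transcription factors of the SOX family, were 2.07-fold and 2.05-fold higher, and the 3 probe sets of each at or above the level minimum all gave higher values, from 0.39 to 1.05 for SOX4 and from 0.37 to 1.04 for SOX11 on the log2 scale. MEF2C, a transcription factor of muscle and other mesodermal lineages, was 1.93-fold higher, with its second probe set above the level minimum at 0.25. SKIL, a repressor of SMAD signalling, was 1.95-fold higher by its brightest probe set. Its other probe sets lay below the level minimum, the lowest at −0.08. ENPP1, a pyrophosphate-generating ectoenzyme, was 2.32-fold higher, SPP1, which encodes the matrix protein osteopontin, was 2.11-fold higher, and the remaining named genes were C1orf54 at 2.23-fold, CNIH3 at 1.98-fold and SMPDL3A at 1.95-fold. The other probe set of ENPP1, below the level minimum, was at −0.03, and the lowest probe set of SEC24D, also below it, was at −0.12. SPP1, C1orf54, CNIH3 and SMPDL3A were each measured by 1 probe set.

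Genes lower with ethanol were fewer. OXTR, the oxytocin receptor, was at 8.74 in the control and 7.60 with ethanol, or 2.20-fold lower. ADAMTS1, a secreted metalloprotease, was 2.19-fold lower, TSPYL4 was 1.98-fold lower, and EDN1, the precursor of the vasoconstrictor endothelin-1, was 1.82-fold lower. Each of these 4 genes was measured by 1 probe set.

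**Figure D1:**
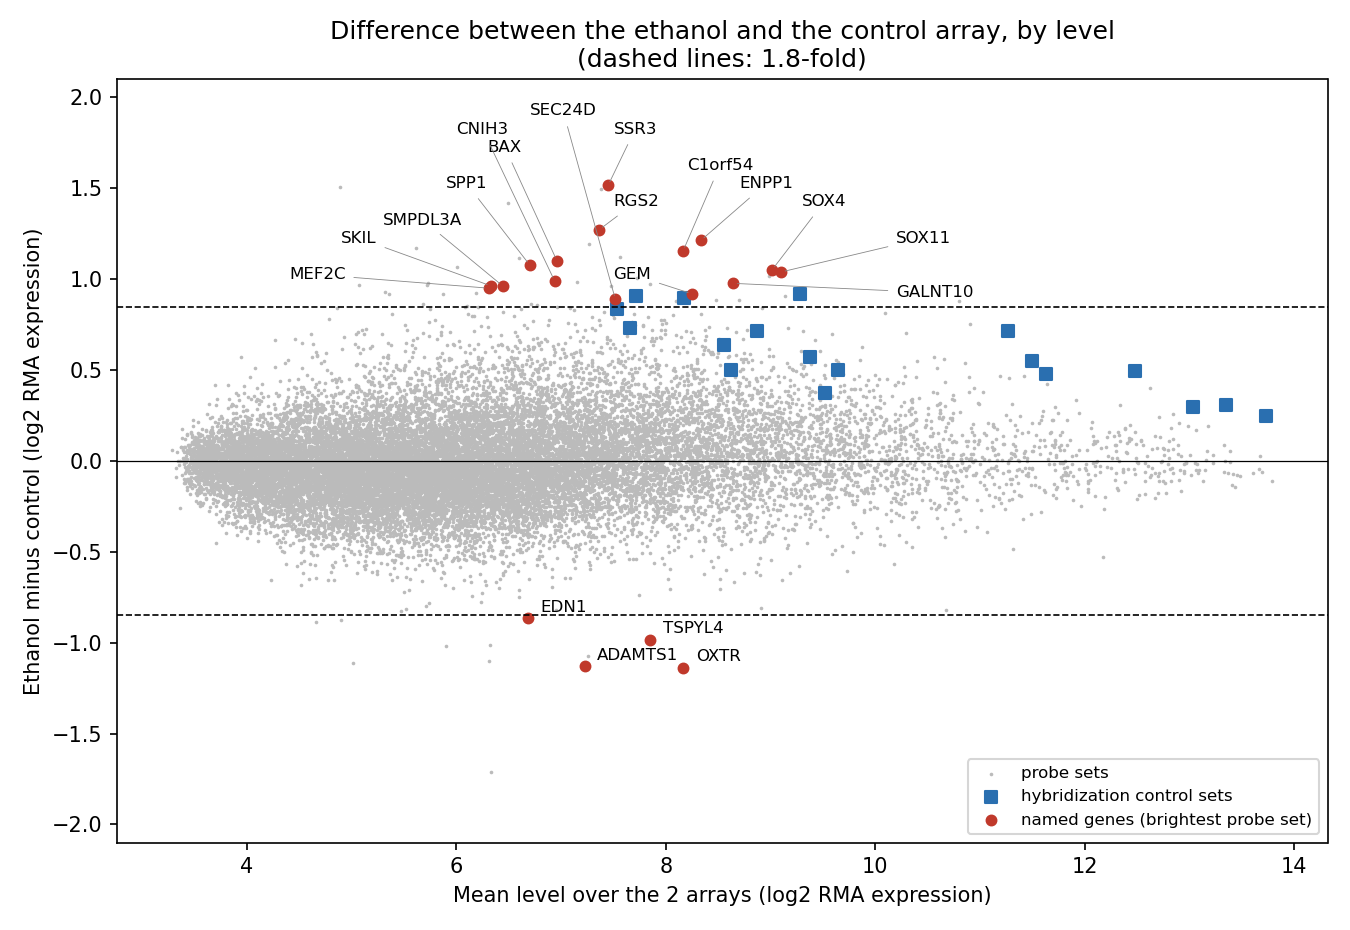
Difference between the ethanol and the control array (vertical axis, log2 RMA expression) against the mean level over both arrays (horizontal axis, log2 RMA expression), with 1 grey point per probe set, named genes in red, hybridization control sets as blue squares and dashed lines at 1.8-fold. SSR3 lies highest of the named genes at 1.52, OXTR lowest at −1.14, and all 18 hybridization control sets lie above 0.

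Of 38 gene lists with enough genes, 11 stood apart from random lists of matched level, 8 higher and 3 lower with ethanol, against 1.9 if genes were independent. The differences within these lists were small, and few members passed 1.8-fold. With probe sets whose IDs end in _s_at or _x_at removed, which left 4048 of 7001 genes, 2 of the 11 stood apart. These were the lists of endoplasmic reticulum chaperones and of mitosis. The metallothionein and neurotransmitter lists kept under 5 genes and gave no percentile in that setting. Read from each gene's second probe set, 2 of the 7 lists with at least 5 such genes stood apart, the matrix proteases and mitosis.

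Genes of the extracellular matrix were higher with ethanol. The list of fibrillar collagens and matrix had a median difference of 0.24 on the log2 scale, or 1.18-fold, above all 10000 random lists (percentile 100), and 23 of its 30 genes at or above the level minimum were higher. COL3A1, the main chain of type III collagen, was 1.58-fold higher, and its 3 probe sets above the level minimum were at 0.66, 1.01 and 1.12. The IDs of all 3 end in _s_at or _x_at, and a dimmer COL3A1 set of the other type was at −0.027. LOXL1, a collagen and elastin crosslinking enzyme, was 1.61-fold higher. POSTN, which encodes periostin, went the other way at −0.55. Of 32 measured members, 2 passed 1.8-fold and 30 did not. One was SPARC, a collagen-binding matrix protein, whose brightest probe set was 1.84-fold higher while its other probe set, also above the level minimum, was at −0.66. The other was LUM, the proteoglycan lumican, at 4.13 in the control and 5.64 with ethanol, below the level minimum. Without the _s_at and _x_at sets the list's median was 0.12, at percentile 96.4. Read from the second probe sets of 23 genes it was 0.11, at percentile 81.0, against 0.25 from the brightest sets of those genes.

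The list of matrix proteases and inhibitors had a median difference of 0.18, at percentile 99.2, with 13 of 18 genes higher. PLAU, the urokinase plasminogen activator, was 1.85-fold higher, with its 2 probe sets, both _s_at, at 0.67 and 0.89, and MMP14, a membrane-anchored collagenase, was at 0.43. ADAMTS1 was 2.19-fold lower and MMP3, stromelysin-1, was at −0.53. The percentile was 77.9 with the mean in place of the median, 92.5 with the median over a gene's probe sets and 95.8 without the _s_at and _x_at sets. Genes of the Wnt pathway had a median of 0.26, at percentile 99.95, with 9 of 15 genes higher and 0 of 22 measured members beyond 1.8-fold. The receptors FZD7 and FZD6 were at 0.60 and 0.57 and the ligand WNT5A at 0.56, but the other probe sets of FZD7 and WNT5A were at 0.088 and 0.063. DKK1, a secreted Wnt inhibitor, was at 11.1 in the control and 10.3 with ethanol, a difference of −0.82. The Wnt median was −0.0024, at percentile 45.6, without the _s_at and _x_at sets, and the list did not stand apart by its mean.

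Chaperones of the endoplasmic reticulum and genes of its degradation pathway were higher with ethanol. Their median difference was 0.18, or 1.14-fold, at percentile 99.2, and 14 of 18 genes were higher, with 0 of 20 measured members beyond 1.8-fold. PDIA4, a protein disulfide isomerase, was at 0.58 and HSP90B1, the chaperone GRP94, at 0.55. XBP1, a transcription factor of the unfolded protein response, was at 0.33. CALR, calreticulin, was at −0.39 by its brightest probe set, and its highest probe set was at 0.43. This list stood apart in all 10 alternatives run for it, between percentiles 98.1 and 99.97. Among these, centring and matching on probe set type left the comparison nearly unaltered and are weak checks. Read from second probe sets it did not, at percentile 97.3, and the 7 genes concerned had a median of 0.25 from those sets and −0.015 from their brightest sets.

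Genes of the cytosolic heat shock response had a median of 0.22, at percentile 99.8, with 11 of 15 genes higher and 0 of 16 measured members beyond 1.8-fold. The mitochondrial co-chaperone HSPE1 was at 0.54, CHORDC1 at 0.47 and HSPH1 at 0.40, and the small heat shock protein CRYAB was at −0.54. The median turned to −0.14 without the _s_at and _x_at sets, and the list did not stand apart with the median over a gene's probe sets. Lysosome and autophagy genes had a median of 0.13, at percentile 98.0, with 18 of 25 genes higher. WIPI1, ATG7 and ATG12, which act in autophagosome formation, were at 0.82, 0.57 and 0.51, and the lysosomal channel MCOLN1 was at −0.40. This list no longer stood apart in 5 of the 10 alternatives, with its lowest percentile at 79.6.

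The genes of ethanol and aldehyde metabolism at or above the level minimum were all higher with ethanol, 8 of 8, with a median of 0.22, or 1.17-fold, at percentile 98.95. Catalase (CAT), which breaks down hydrogen peroxide and can oxidize ethanol, was 1.41-fold higher, and ALDH2, the mitochondrial enzyme that clears acetaldehyde, was 1.35-fold higher. ALDH3A2 was at 0.42 and ALDH7A1 at 0.26. ADH5, a widely expressed alcohol dehydrogenase, was at 10.1 on both arrays, a difference of 0.0093. CYP2E1, the ethanol-oxidizing cytochrome P450, was below the level minimum at 4.88 in the control and 4.68 with ethanol. None of the 17 measured members passed 1.8-fold. Over all 17 the median was 0.0052, at percentile 71.3, and the list also did not stand apart without the _s_at and _x_at sets or with the median over a gene's probe sets.

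Genes of mitosis were lower with ethanol. Their median difference was −0.13, at percentile 0.1, and 21 of 28 genes were lower, with 0 of 29 measured members beyond 1.8-fold. CDC20, an activator of the anaphase-promoting complex, was 1.63-fold lower, and AURKB and CCNB2, which encode Aurora kinase B and cyclin B2, were at −0.42 and −0.41. TOP2A, DNA topoisomerase II alpha, was at 0.57. The list stood apart in all 10 alternatives, between percentiles 0.09 and 0.39, with centring and matching on probe set type again as weak checks. Genes of DNA replication had a median of 0.021, at percentile 58.2, with 13 of 24 higher. Members named from those at or above the level minimum were RRM2 at −0.45, POLA2 at −0.37, MCM6 at 0.32 and TK1 at −0.25.

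Metallothioneins, small metal-binding proteins, had a median of −0.36, with 0 of 10000 random lists as low, and 5 of 8 genes were lower. MT2A was at 12.4 in the control and 11.9 with ethanol, a difference of −0.53, MT1X was at −0.49, MT1G at −0.38 and MT1H at −0.36. Of the remaining 4 genes, 1 was lower and 3 were slightly higher. Metallothionein genes are near-identical in sequence and their probe sets can bind each other's transcripts, so these are not separate measurements. Neurotransmitter and purinergic receptors had a median of −0.27, at percentile 0.33, over 7 of 25 measured genes, with HTR3A at −0.49, KCNMA1 at −0.43, P2RX1 at −0.28 and GRIN2A at −0.27. Over all 25 genes the median was −0.066, at percentile 30.6. The type I interferon response had a median of 0.11, at percentile 97.8, with IFITM1 at 0.42, PSMB8 at 0.42, IFIT2 at 0.40 and OAS2 at −0.39. Over all 32 measured genes its median was −0.050, at percentile 41.9, and the list stood apart in 4 of its 10 alternatives.

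**Figure D2:**
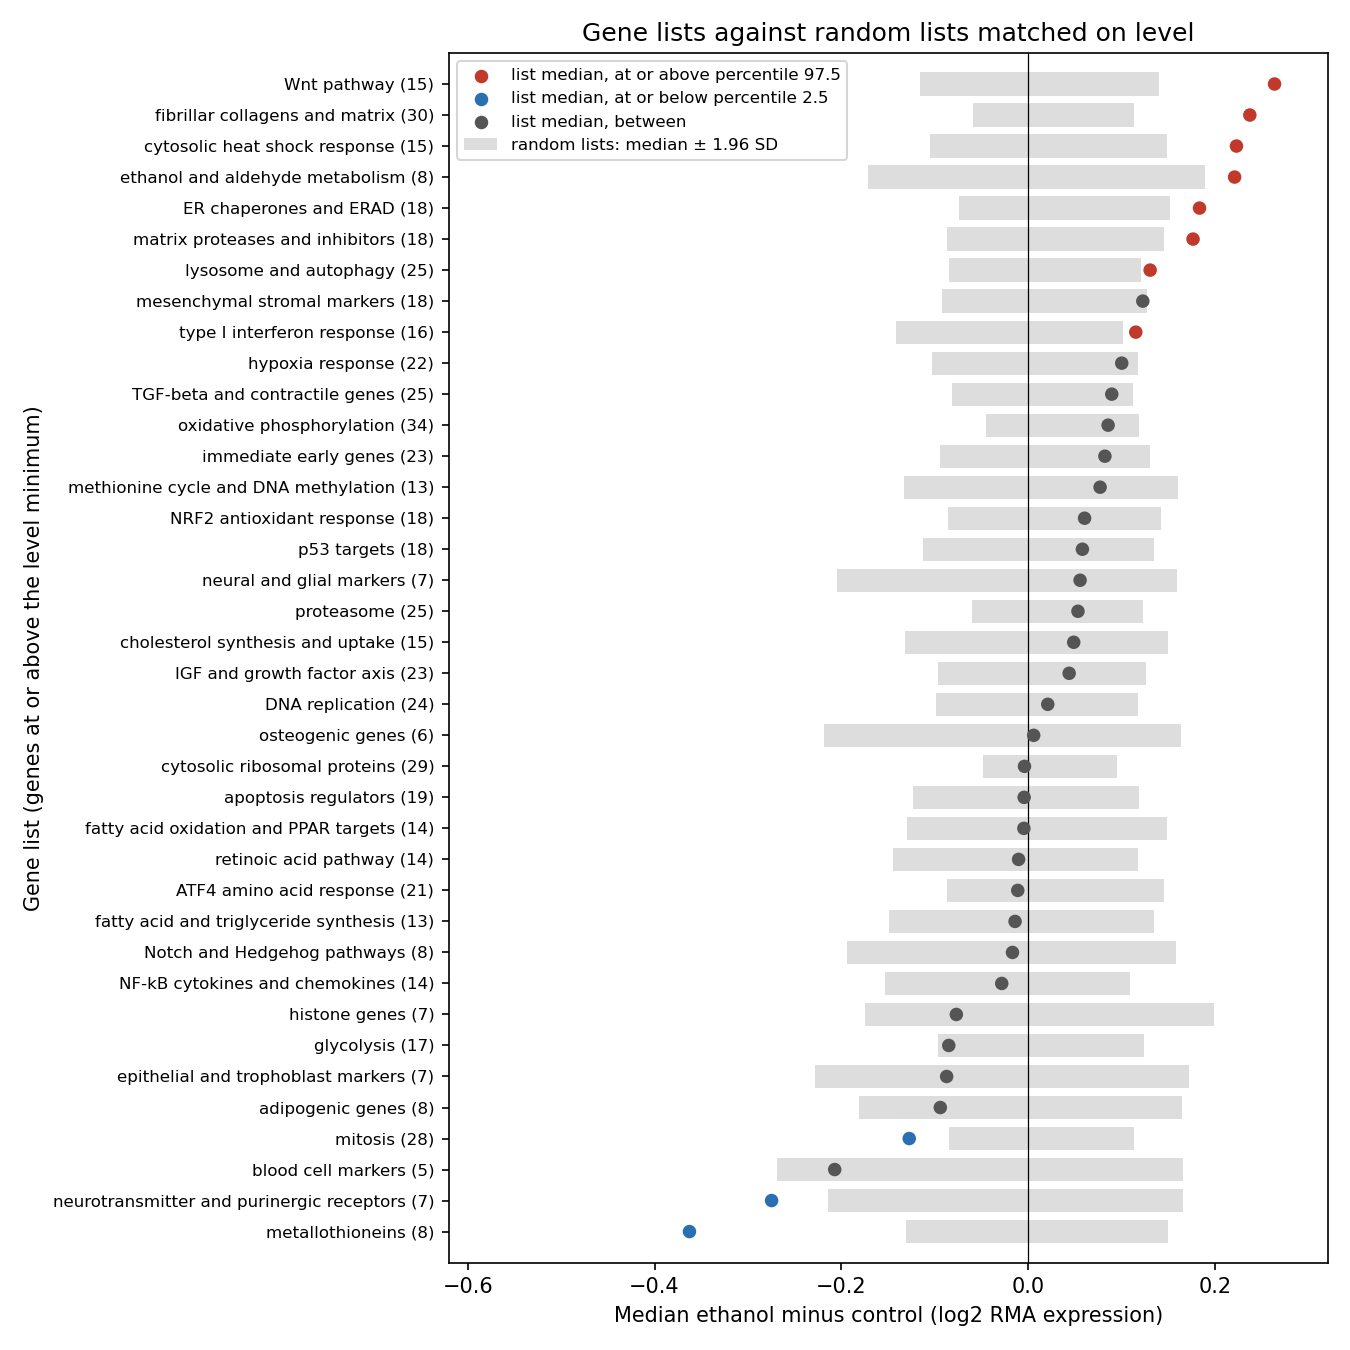
Median difference between the ethanol and the control array for each gene list (horizontal axis, log2 RMA expression; 1 row per list with the number of genes at or above the level minimum), with grey bars for random lists of matched level (median ± 1.96 SD). The 8 red lists lie above the random lists, from 0.11 to 0.26, and the 3 blue lists below, from −0.36 to −0.13.

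The remaining 27 lists lay between the percentile limits. Mesenchymal stromal markers were at percentile 96.6 with a median of 0.12, hypoxia genes at 93.9, TGF-beta and contractile genes at 92.4, oxidative phosphorylation at 87.6 and immediate early genes at 85.9. Glycolysis was at percentile 3.31 with a median of −0.085, and 13 of its 17 genes were lower. Several stress lists did not stand apart. The NRF2 antioxidant response was at percentile 70.7 and the ATF4 amino acid response at 24.2. The p53 targets were at 75.9 and apoptosis regulators at 48.7. BAX was the 1 member beyond 1.8-fold in each of the last 2 lists, as SKIL was among TGF-beta and contractile genes. Lipid lists were at 70.0 for cholesterol synthesis, 45.7 for fatty acid synthesis and 41.9 for fatty acid oxidation, and housekeeping lists at 24.3 for ribosomal proteins and 68.1 for the proteasome. Methionine cycle genes were at 79.8, NF-kB cytokines at 46.5, the IGF and growth factor axis at 68.9, the retinoic acid pathway at 51.9, Notch and Hedgehog pathways at 50.5 and histone genes at 16.1. Lineage lists were at 64.0 for osteogenic genes, with SPP1 as the 1 member beyond 1.8-fold, 14.2 for adipogenic genes and 79.1 for neural and glial genes.

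Few markers of other cell types, or of pluripotency and germ cells, reached the level minimum. Of 26 epithelial and trophoblast markers measured, 7 reached the level minimum, with a median at percentile 25.7, and KRT18, a keratin of simple epithelia, was at −0.57. Of 18 blood cell markers 5 reached it, at percentile 6.03. Of 13 endothelial markers 3 did, and of 18 pluripotency and germ markers 4 did, which was too few for a percentile. KIT, the receptor often used to select such stem cells, was at 4.84 in the control and 4.98 with ethanol. KIT was singled out after its values were seen.

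**Figure D3:**
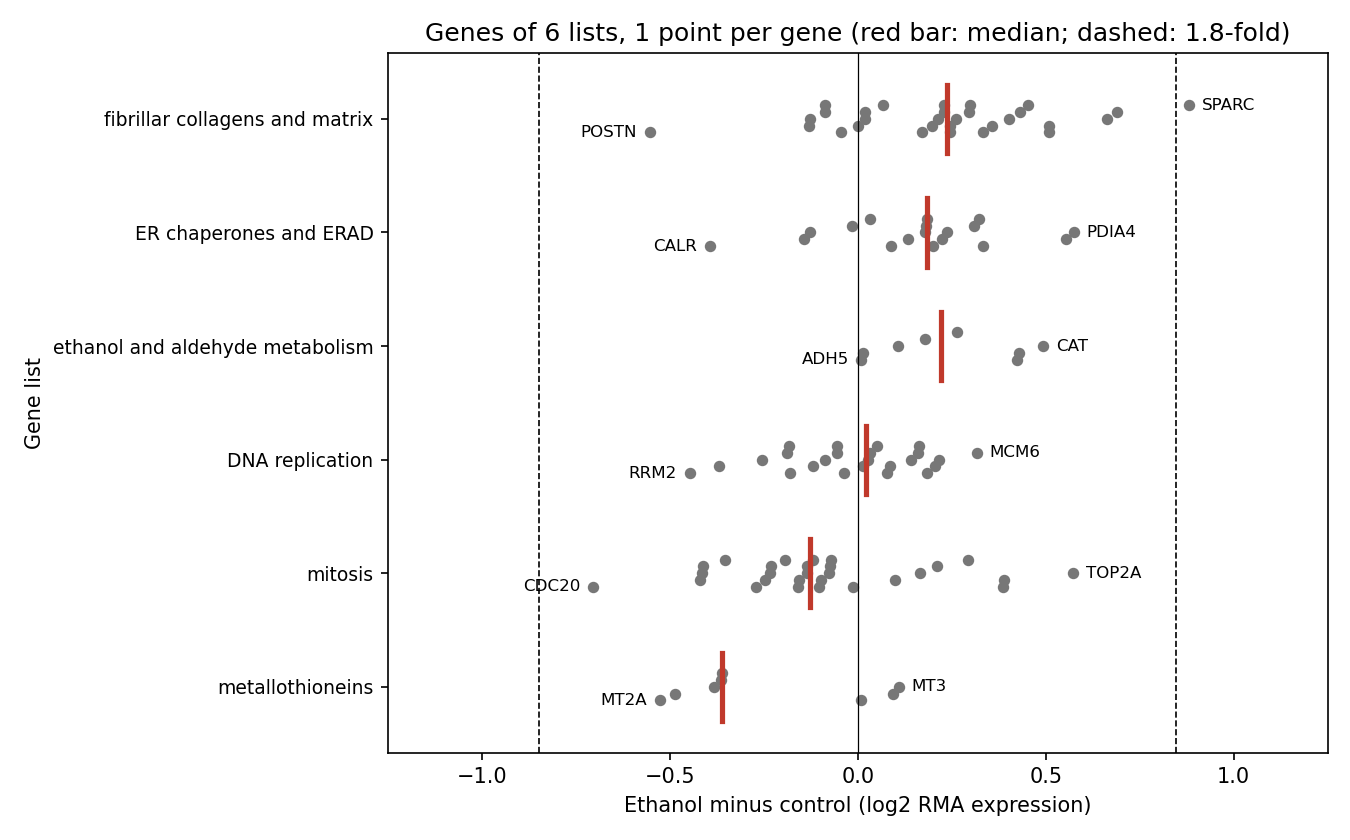
Difference between the ethanol and the control array (horizontal axis, log2 RMA expression) for each gene at or above the level minimum in 6 lists (vertical axis), with 1 grey point per gene, a red bar at the list's median and dashed lines at 1.8-fold. Matrix genes centre on 0.24 and mitosis genes on −0.13, with DNA replication genes on 0.021.

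The arrays carry 2 internal measures of error. In 1974 genes with a second probe set at or above the level minimum, the differences of the 2 brightest probe sets correlated with r = 0.300 (Spearman rho = 0.278) across genes, which are not independent replicates, and had the same direction in 59.8%. Of 7 genes beyond 1.8-fold with such a second probe set, 6 had the same direction in it and 2, BAX and SOX11, passed the threshold in it. The 18 sets for hybridization controls, bacterial and phage transcripts added to the labelled sample, were all higher on the ethanol array, by 0.25 to 0.92 on the log2 scale, and 3 of them passed 1.8-fold. The 24 sets for the poly-A controls dap, lys, phe and thr were all lower, with a median of −0.34. The amounts of labelled RNA and of added controls per array are not given in the sources used here, so a difference in them between the arrays stays open beside every value. The 3 GAPDH and 3 beta-actin sets lay between −0.19 and 0.043. The 3′ set differed from the 5′ set by −0.034 for beta-actin and −0.030 for GAPDH between the arrays.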

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

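The hybridization controls bioB, bioC, bioD and cre, which enter no comparison of conditions, differed between the arrays with a median of 0.56 on the log2 scale, higher with ethanol in 18 of 18 sets. They were singled out because a signal outside the main measurement exceeded that of the control array. Their median level was 9.21 on the control array and 9.72 on the ethanol array. Of 12 ribosomal RNA sets, 1 was higher and the median was −0.31, and the trp sets, near the bottom of the scale, had a median of −0.054.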

How the results depend on the processing

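The matching of random lists on probe set type was chosen after the data were seen. Against 58 probe sets beyond 1.8-fold, the number was 372 at 1.5-fold, 27 at 2-fold, 23 with 32 added before log2 and 24 without _s_at and _x_at sets. Against 30 genes beyond 1.8-fold, it was 187 at 1.5-fold, 12 at 2-fold and 12 with 32 added, and 1 gene, BAX, had 2 or more probe sets that all passed. The other 10 counts of probe sets and genes stayed within 1.5 times, and the share of higher genes was 69.6% with the median over a gene's probe sets. The lists standing apart numbered 4, of which 2 were among the 11, without _s_at and _x_at sets, and 8 to 12 in the other 9 settings. That setting also turned the medians of the heat shock list to −0.14 and of the Wnt list to −0.0024, and the values of ENPP1 to −0.030 and SPARC to −0.66. For ENPP1 and SPARC another probe set then stood for the gene, and for the counts and lists fewer genes or other probe sets entered, which the data do not separate. Dropping the level minimum turned the interferon median to −0.050 by adding dimmer genes. Without _s_at and _x_at sets the metallothionein and neurotransmitter lists kept under 5 genes and gave no percentile. Of 180 genes recomputed, quantile normalization, centring and lowess subtraction moved 0 by more than 0.20 on the log2 scale, the robust SD of gene differences. The median over a gene's probe sets moved 37 of the 180 and adding 32 moved 17. Removal of _s_at and _x_at sets moved 23, reversed ENPP1 and SPARC and left 94 within that spread. Genes with only _s_at or _x_at sets, such as SSR3 and BAX, gave no value in that setting and were not checked by it. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Dim probe sets limit what can be seen, since signal over background is not given by the values.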

Other observations

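Some single probe sets differed more than the brightest probe set of their gene. These were chosen after their values were seen. A probe set of NRG1, which encodes the growth factor neuregulin-1, was at 7.18 in the control and 5.47 with ethanol, a difference of −1.71. The brightest NRG1 probe set was at −0.39 and another above the level minimum at −0.45. The dimmer NRG1 sets, below that level, were at 0.49, −0.37 and −0.18. For FGF2, fibroblast growth factor 2, one probe set was at −1.02 and the brighter one at 0.11. One probe set of SLC7A8, an amino acid transporter, was 2.82-fold higher. Of 1974 genes with several probe sets at or above the level minimum, 4 were more than 1.5-fold higher in all of them, BAX, COL3A1, PLAU and FBXO21, and 1 was lower, MFAP5, a microfibril component, with 3 probe sets between −1.10 and −0.59. In 6 genes the 2 brightest probe sets went opposite ways by more than 2-fold in total, among them SPARC, FGF2 and the RNA helicase DDX17. Below the level minimum, 6 genes passed 1.8-fold: LUM, RNF128, MFHAS1 and PLA2G4A were higher, and ANKRD1 and PTX3 lower.

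In what follows, 5 tests were chosen after the data or the result they bear on were seen: the lowess test of the skew, the matching on probe set type, the readings of the protease and heat shock lists from second probe sets, and the comparison of mitosis with DNA replication. More genes beyond 1.8-fold were higher than lower. After lowess subtraction of a trend with level, 79.3% of the called genes were higher (exact 95% interval 60.3 to 92.0%, counting error only). The subtraction moved each gene by at most 0.057 on the log2 scale, against a threshold of 0.85. These values argue against a smooth trend with level as the cause of the skew between these 2 arrays. Whether ethanol itself gave the skew stays open, since there was 1 array per group.

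The 11 lists standing apart may in part reflect properties of single probe sets. Matching random lists on probe set type left 11 of 11 standing apart but moved the random medians by at most 0.010, too little to decide. Removing the _s_at and _x_at sets left 2 of the 11. In that setting the metallothionein and neurotransmitter lists kept under 5 genes and gave no percentile, so they did not fail it. Probe set type thus stays open. Read from each gene's second probe set, 6 of the 7 lists with enough genes had the direction of the full list (exact 95% interval 42.1 to 99.6%). Most of these lists were higher ones, and random lists read from second probe sets also had medians above 0, from 0.044 to 0.067. The count of directions therefore decides little. Mitosis, at percentile 0.47, and the proteases, at 99.45, stood apart in that reading. The proteases did not with the median over a gene's probe sets or without the _s_at and _x_at sets. Probe-specific hybridization thus stays open for the proteases, for lysosome and autophagy at percentile 96.9, Wnt at 85.9, matrix at 81.0 (median of 0.11 from second and 0.25 from brightest sets of 23 genes) and endoplasmic reticulum chaperones at 97.3 (0.25 and −0.015, 7 genes), and it is a candidate explanation for the heat shock list, at 9.045. A difference between single cultures, with 1 array per group, cannot be told apart from ethanol.

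Mitosis genes were lower while DNA replication genes were not. For the 8 mitosis genes with a second probe set, probe-specific hybridization is unlikely to be the cause of the lower values. Their second probe sets gave a median of −0.17, below 0 by more than the random-list SD of 0.10. The other mitosis genes and the DNA replication list were not read in this way. Probe-specific hybridization thus stays open for those genes and for the contrast of the lists. Fewer cycling cells would be expected to lower both lists. The DNA replication median exceeded the mitosis median by 0.15, or 1.98 random-list SDs of the difference, just under the 2 SDs set as the bound, so this explanation stays open.

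The lower value of ANKRD1, a YAP target, prompted the hypothesis that target genes of the transcriptional coactivators YAP and TAZ might be lower with ethanol. A list of 21 such genes, written after that value was seen and leaving out ANKRD1, had 14 genes at or above the level minimum, of which 10 were lower. Its median was −0.095, at percentile 3.77, which missed the bound of 2.5 set before the test. AXL was at −0.61, CCN2 at −0.35 and CCN1 at −0.27, MYOF was at 0.36, and 0 of the 14 passed 1.8-fold.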
